A study of Mus musculus with 8 samples.

How the data were processed

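RNA of lung mesenchymal cells was profiled on 8 arrays, 4 from control mice given phosphate-buffered saline and 4 from mice given bleomycin, all taken on day 10. Per the labels' protocols, total RNA was purified on silica columns and biotinylated cRNA was made from 100 ng of it. The deposited values are 1 number per probe set and array. They are taken to be log2 intensities because they run from 0.24 to 13.58, and the table names no scale. The background correction, summarisation and normalization that the authors used are not given in the sources used here. Groups and replicate numbers come from the sample titles. Arrays give no read depth, and only the number of arrays limits the precision. Detection calls and background levels were not used here, so the least bright genes cannot be told from background.

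The table held 41345 rows. The probe annotation used here paired 23521 of them with 1 gene and 1814 with several, and 16010 rows had no gene in it. Rows with several genes or none were not named and were left out of the main test. Each of the remaining 22180 genes was represented by its probe set with the highest mean over all 8 arrays, and 1082 genes had more than 1 probe set. Of the named genes, Adamts14, Lgr5, Nrxn2, Pole, Rrm2 and Slc1a5 had a second, dimmer probe set that did not pass, with log2 differences of 0.316, 0.295, 0.0106, 0.0168, 0.0859 and -0.0456. Those of Cyp2f2, Ereg and G0s2 passed with smaller differences than the probe set used. By Entrez identifier, 21994 genes matched the RefSeq gene table of GRCm38.p6, which called 18964 of all tested genes protein-coding. No genome build is named with the values, so no coordinates are given.

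Choices made before the data were examined were the groups, the test, the gene lists, the rule for named genes and most alternatives. Values were to be used as deposited if they were log2 and the arrays shared their median to within 0.1. The rule did not say over which rows. The array medians ranged over 0.0813 for rows with 1 gene and 0.071 for the tested genes, but over 0.109 for all rows, so the rule was met on the rows that were tested and missed on the whole table. The values were used as deposited, and quantile normalization is among the alternatives. The median of the rows without a gene was lower in bleomycin arrays by -0.229 in log2 units.

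Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 44 lists with at least 5 measured members. Camera asks whether a list's genes moved more than the other genes. The 44 lists and a set of sex-linked genes were written from general knowledge of lung cell types and bleomycin injury. They held 869 genes, of which 799 were measured under the same symbol. The rest, among them Spp1, Fbn1, C3 and the haemoglobin genes, were not analysed here. Some lists share members, as stated where it matters. Figures were drawn with matplotlib 3.10.9.

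The genes named are the 12 largest rises and the 12 largest falls among genes that passed and whose groups did not overlap, the genes of the sorting gate, the mesenchymal genes Pdgfra, Pdgfrb, Col1a1 and Acta2, the sex-linked genes, and from each list up to 3 passing members with the largest change in the majority direction and up to 2 in the other. Where a list had 5 or fewer passing members all of them were eligible, and where none passed the 2 brightest were. Not every eligible gene is named, and which of them to leave out was settled after their values were seen, with preference for those whose call held in every fit that left out 1 array. Predicted gene models were counted and not described. Genes named outside the rule are marked where they appear. Near-identical copies, such as those of Lyz1, Hspa1a and the actin genes, may share signal.

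The test was checked on simulated data with the real genes and group sizes, in which 200 of 22180 genes were changed. It recovered 53.7% of 1.5-fold, 86.6% of 2-fold and 100% of 4-fold changes, and 3.03% of its calls were false. The simulated noise was independent between genes and between arrays, so these rates need not hold for the real data. The alternatives were the replicate number as a block, quantile normalization, median centring, leaving out the dimmest 30% or 50% of genes, other choices of probe set, a trended and robust eBayes, array weights, stricter thresholds, each array left out, camera with an estimated correlation and fry. After seeing the data, fits with replicates 1 and 2 against 3 and 4 as a block or alone, without control replicates 1 and 2, with a marker covariate, and on protein-coding genes alone were added.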

Results

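Gene expression was measured in lung mesenchymal cells of C57BL/6J mice kept under specific pathogen-free conditions and 11 weeks old. The mice had received phosphate-buffered saline or bleomycin through the trachea. Bleomycin is a DNA-damaging antibiotic that injures the lung and is widely used to provoke fibrosis in mice. On day 10 the cells without CD45, CD31 and EpCAM on their surface were isolated by flow cytometry. These antigens mark leukocytes, endothelium and epithelium, so the gate leaves fibroblasts, pericytes and smooth muscle. Labelled cRNA from 100 ng of total RNA was hybridised to 1-colour oligonucleotide arrays, with 4 control and 4 bleomycin arrays. The number of arrays limits the precision. The labels do not say whether the replicates came from separate animals. The p-values then measure only the spread between these samples, which may be technical. The comparison asked which transcripts differ between mesenchymal cells of injured and control lungs.

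The sorted samples of bleomycin-treated lungs had higher levels of extracellular matrix, contractile, cell cycle, interferon and inflammatory fibroblast genes, and lower levels of alveolar fibroblast and immediate early genes, by limma's camera with a preset correlation. None of the 44 gene lists passed with an estimated correlation, where the smallest adjusted p was 0.13. Markers of alveolar epithelium and blood endothelium, cell types that the gate should remove, were also lower. Among 22180 genes, 2022 were higher and 1828 lower in the bleomycin samples (limma, Benjamini-Hochberg adjusted). Of these, 440 were higher and 282 lower by over 2-fold, and 90 were higher and 25 lower by over 4-fold. In 1915 of the higher and 1728 of the lower genes the groups did not overlap. Among all tested genes the groups did not overlap in 23.5%, against 2.86% by chance. The median standard error of a log2 difference was 0.116.

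The first principal component held 58.6% of the variance and separated the groups. Control arrays lay between -31.6 and -29.3 on it and bleomycin arrays between 15 and 41.7, with bleomycin replicate 4 nearest the controls. The second component held 11.1% and set replicates 1 and 2 of both groups apart from replicates 3 and 4. Within replicates 1 and 2 alone, 838 genes were higher and 833 lower. Within replicates 3 and 4 alone, 503 were higher and 220 lower. Of the 162 genes named in the text, 23 lost their call in the former pair and 70 in the latter, with 2 arrays per group. With these pairs of replicates as a block, 2293 were higher and 2168 lower. Without control replicates 1 and 2, whose epithelial and endothelial markers stood above those of the other controls, 1205 were higher and 992 lower. There 13 named genes lost their call, namely Vtn, Lyve1, Cxcl15, Mmp3, Lrrc17, Pdia6, Egr3, Ndufa4, Tyrobp, Gzma, Ppbp, Prss8 and Smo (adjusted p between 0.0504 and 0.182). With the mean of those markers as a covariate, which itself differs between the groups, 77 were higher and 12 lower. These fits were chosen after seeing the data. The balance of the directions depended on the scaling, since centring each array on its median gave 1623 higher and 2314 lower genes.

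**Figure D1:**
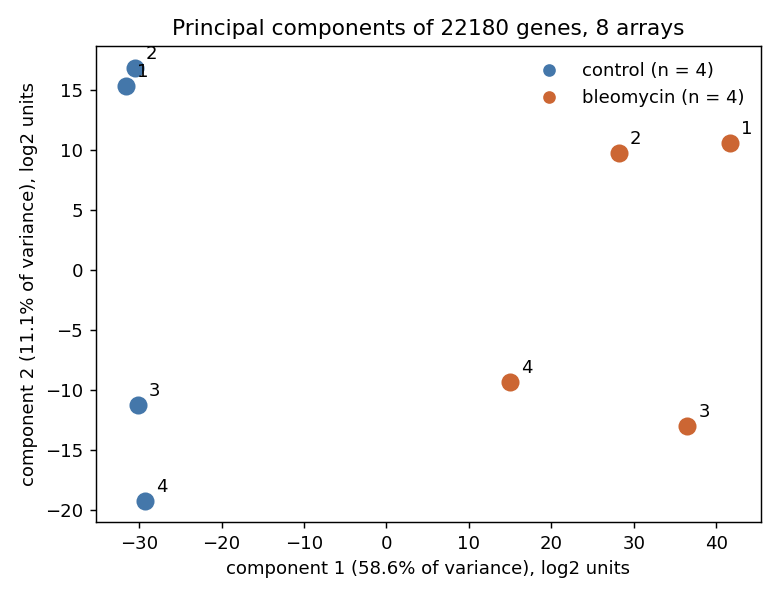
Scores of the 8 arrays on the first and second principal components of the tested genes, in log2 units, with points coloured by group and numbered by replicate. The groups separate on the first component, which holds 58.6% of the variance, and replicates 1 and 2 of both groups lie above replicates 3 and 4 on the second, which holds 11.1%.

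Chl1, which encodes a neural cell adhesion molecule, rose most. Its level went from 3.03 ± 0.14 to 9.10 ± 0.54 (log2, mean ± SD, n = 4 each; limma adjusted p = 6.58e-07). The control level lay below the medians of the probe sets without a gene on the control arrays (4.44 to 4.52), so the size of this rise is uncertain, as it is for Frzb, Tnfsf18 and Tfap2a, whose control levels were 4.12, 4.05 and 3.16. The same limit holds for Mmp13, Cfi and S100b, named further on, with control levels of 3.54, 4.03 and 3.80, and for Gzma and Ppbp, with bleomycin levels of 3.98 and 4.01. The next largest rises were in Rgs16, a regulator of G protein signalling, by 4.32 ± 0.17 (log2 difference ± SE, as in all values below), in Frzb, a secreted Wnt antagonist, by 4.29 ± 0.18, and in the thrombospondin Thbs4 by 4.21 ± 0.26. Tnfsf18, the ligand of the T cell receptor GITR, rose by 4.20 ± 0.35 and the transcription factor gene Tfap2a by 4.18 ± 0.26. P4ha3, a subunit of collagen prolyl 4-hydroxylase, and Cxcl13, a B cell chemokine, both rose by 3.88. The BMP antagonist Grem1 rose by 3.77 ± 0.29, the activin-binding protein Fst by 3.75 ± 0.20, the EGF receptor ligand Ereg by 3.72 ± 0.19 and the collagenase Mmp8 by 3.61 ± 0.26. The adjusted p of these 12 genes was at most 8.47e-05. A second, dimmer probe set of Ereg rose by 1.26, so the size of that rise depends on the probe set.

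The largest falls were in the lysozyme gene Lyz1, by -2.95 ± 0.39, in Hc, which encodes complement C5, by -2.76 ± 0.39, and in the surfactant protein gene Sftpa1 by -2.69 ± 0.36. Slc34a2, a phosphate transporter of alveolar type 2 cells, differed by -2.69, the carbonyl reductase Cbr2 by -2.62, the cytochromes Cyp4b1 and Cyp2f2 by -2.45 each and Lamp3 by -2.44. Lyz1, Sftpa1, Slc34a2 and Lamp3 are on the alveolar epithelium list and Cyp2f2 is on the airway epithelium list, both of which were lower as a whole (below). Genes on neither list also fell. Rasgef1b, a Ras exchange factor, differed by -2.54 ± 0.21, the glutamate receptor gene Gria1 by -2.54 ± 0.28, the neurexin Nrxn2 by -2.43 ± 0.13 and the collagen galactosyltransferase Colgalt2 by -2.40 ± 0.26. The adjusted p of these 12 genes was at most 0.00321. Second, dimmer probe sets of Nrxn2 and Cyp2f2 differed by 0.01 (adjusted p = 0.967) and -0.81. Within replicates 3 and 4 alone Slc34a2 differed by -1.78 and Lamp3 by -1.47, and neither passed (adjusted p of 0.0848 and 0.0982). Hc, Sftpa1 and Colgalt2 did not pass there either, at -1.84, -2.05 and -2.56 (adjusted p of 0.061, 0.075 and 0.0549). With the marker covariate Hc, Cbr2 and Cyp4b1 differed by -0.55, -1.36 and -1.27 (adjusted p of 0.437, 0.0801 and 0.199).

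**Figure D2:**
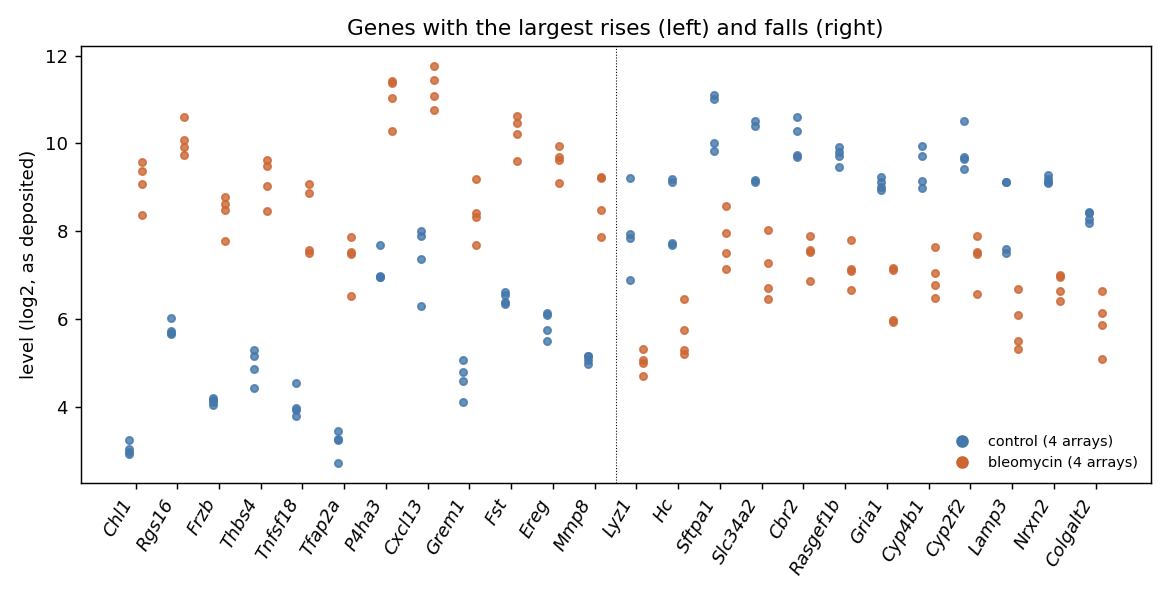
Log2 levels, as deposited, of the 12 genes with the largest rises (left) and the 12 with the largest falls (right), 1 point per array. In each gene the 4 bleomycin points do not overlap the 4 control points, and Chl1 rises from about 3.03 to 9.10.

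Of the 44 gene lists fixed beforehand, 14 were higher and 8 lower in the bleomycin samples by limma's camera with a preset correlation. None passed with the correlation estimated per list, where 8 reached an unadjusted p under 0.05 and the smallest adjusted p was 0.13. By fry, 21 lists were higher and 9 lower. Of the 35 splits of the arrays into 4 and 4, 3 called at least as many lists as the real groups, the real groups included. The gene counts of each list therefore rest on the test of each gene, and the adjusted p with an estimated correlation is given for each list called.

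Most collagen genes rose. Of 25 collagen chains 19 rose and none fell, with a median log2 difference of 0.83 (20 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.81e-13, and adjusted p = 0.198 with an estimated correlation). Col8a1 rose by 2.59 ± 0.22, Col28a1 by 2.40 ± 0.11 and Col12a1 by 2.25 ± 0.15, while Col1a1, already among the brightest genes at 11.94, rose by 0.83 ± 0.12. Of 22 enzymes and chaperones of collagen folding and cross-linking 13 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 2.16e-06, and adjusted p = 0.264 with an estimated correlation). The median of this list was 0.40, and 0.15 with the marker covariate, where its camera call was lost (adjusted p = 0.0791). Besides P4ha3, the prolyl 3-hydroxylase P3h1 rose by 1.02 and the procollagen peptidase Adamts14 by 1.01, and the procollagen peptidase enhancer Pcolce2 fell by 1.19 ± 0.21.

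Among 34 other matrix proteins 18 rose and 4 fell (20 and 6 adjusted over the list alone; camera adjusted p = 1.26e-05, and adjusted p = 0.246 with an estimated correlation). Tenascin C, Tnc, rose by 3.35 ± 0.12 and Cthrc1 by 2.92 ± 0.30, whereas the elastic fibre protein Fbln5 fell by 0.90 and Tgfbi by 0.86. Of 26 matrix proteases and inhibitors 15 rose and 2 fell (16 and 4 adjusted over the list alone; camera adjusted p = 1.23e-05, and adjusted p = 0.228 with an estimated correlation). The collagenase Mmp13 rose by 3.04 ± 0.26 and Adam12 by 2.22 ± 0.29, and the stromelysin Mmp3 fell by 0.52. The 16 basement membrane genes went both ways, with 3 up and 5 down (5 and 5 adjusted over the list alone; camera adjusted p = 0.537). Nid2 rose by 1.06 and Lama5 by 0.93, and Lamc3 fell by 0.90.

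Most contractile genes and most genes of the fibrotic fibroblast state rose. Of 16 contractile genes 11 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 1.85e-07, and adjusted p = 0.246 with an estimated correlation). Acta2, the smooth muscle actin that marks myofibroblasts, rose from 10.12 ± 0.17 to 12.04 ± 0.33 (n = 4 each), or 3.78-fold. The related actin gene Actg2 rose by 2.55 ± 0.31 and the actinin Actn1 by 1.31 ± 0.12. Actin genes are close in sequence, and their probe sets may share signal. Of 17 genes of the Cthrc1-positive fibroblast state of fibrotic lung 14 rose and 1 fell, with a median difference of 2.22 (15 and 1 adjusted over the list alone; camera adjusted p = 1.91e-15, and adjusted p = 0.193 with an estimated correlation). Grem1, Fst and Tnc led this list, which shares 5 members with the matrix proteins, and the leucine-rich repeat gene Lrrc17 fell by 0.71.

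**Figure D3:**
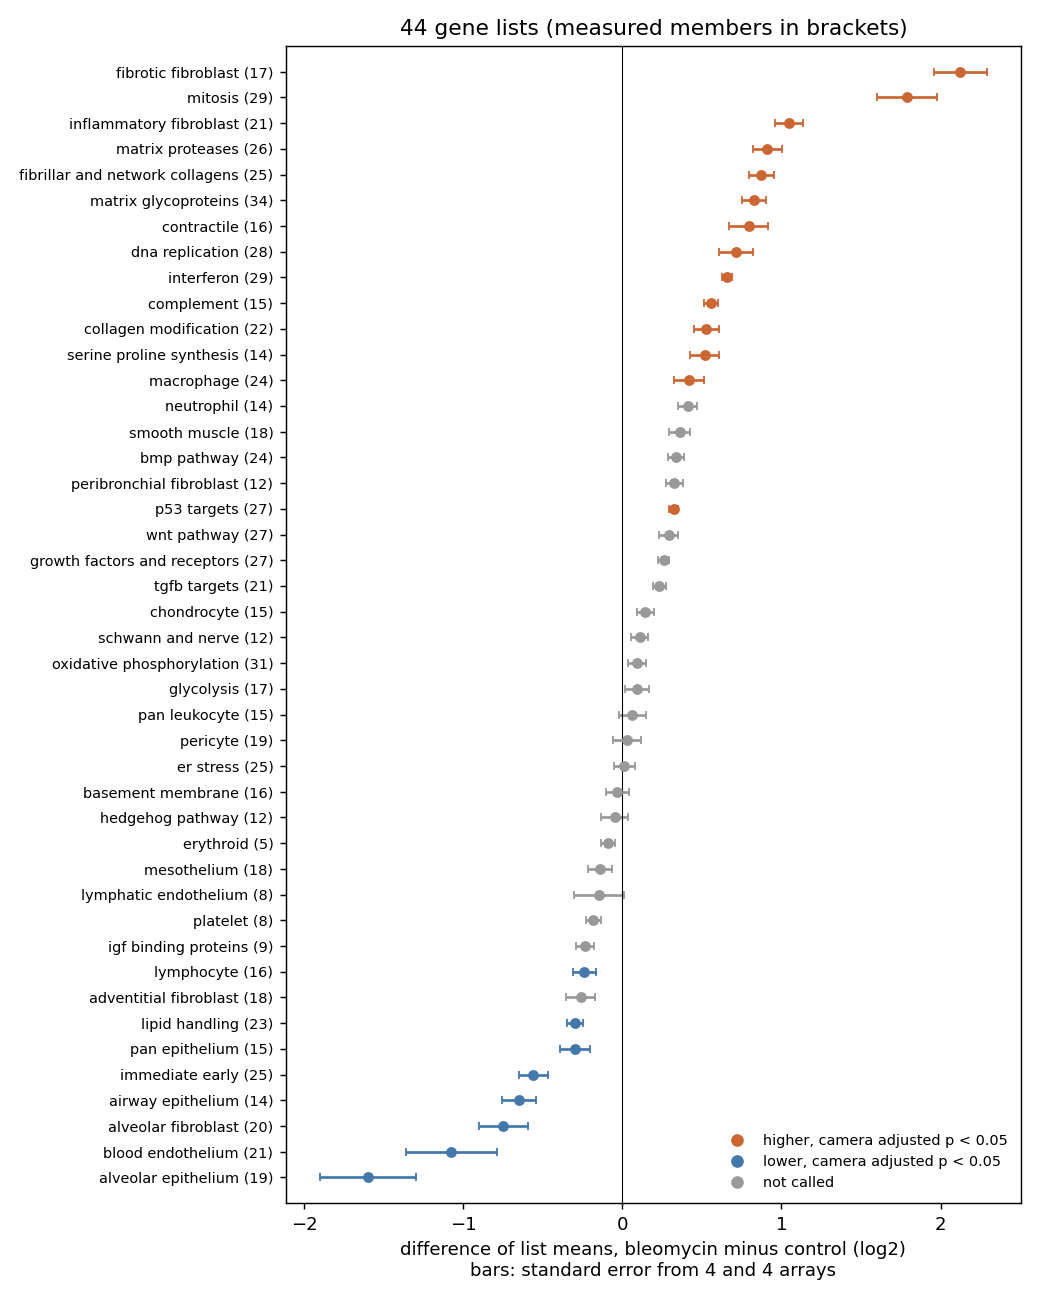
Difference of list means between bleomycin and control arrays (log2) for each of the 44 gene lists, with bars for the standard error over 4 and 4 arrays, ordered by size. Coloured points are the lists called by camera with a preset correlation, 14 higher and 8 lower, and none of these passed with an estimated correlation.

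Inflammatory and interferon genes rose. Of 21 acute phase and chemokine genes of inflammatory fibroblasts 15 rose and none fell, with a median difference of 0.82 (16 and 0 adjusted over the list alone; camera adjusted p = 6.95e-10, and adjusted p = 0.16 with an estimated correlation). After Cxcl13, the serum amyloid gene Saa3 rose by 3.22 ± 0.24 and haptoglobin, Hp, by 1.99 ± 0.16. Of 29 interferon response genes 17 rose and 1 fell (18 and 3 adjusted over the list alone; camera adjusted p = 3.31e-09, and adjusted p = 0.13 with an estimated correlation). The T cell chemokines Cxcl10 and Cxcl9 rose by 3.13 ± 0.16 and 3.01 ± 0.20 and Ifit1 by 1.62 ± 0.08. The transcription factor gene Irf1 fell by 0.63 ± 0.09. Of 15 complement genes 7 rose and none fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.000469, and adjusted p = 0.198 with an estimated correlation). C1qb rose by 2.02, Cfi by 1.53 and C3ar1 by 1.16. Hc, which encodes complement C5 and differed by -2.76, is not on this list. It was uneven among the controls, as the epithelial markers were, at 9.19 and 9.11 on replicates 1 and 2 and 7.73 and 7.69 on replicates 3 and 4. With the marker covariate Hc differed by -0.55 (adjusted p = 0.437). The complement list shares 3 members with the macrophage list, which was also higher (below). Leaving out the dimmer 50% of genes ended the complement call (adjusted p = 0.0567).

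Most cell cycle genes rose. All 29 mitosis genes rose, with a median difference of 1.85 (29 adjusted over the list alone; camera adjusted p = 1.63e-27, and adjusted p = 0.198 with an estimated correlation). The proliferation marker Mki67 rose by 2.94 ± 0.24, the topoisomerase Top2a by 2.78 ± 0.21 and Prc1 by 2.64 ± 0.21. Of 28 DNA replication genes 21 rose and none fell (25 and 0 adjusted over the list alone; camera adjusted p = 1.47e-13, and adjusted p = 0.228 with an estimated correlation), with Rrm2 up by 1.70, Mcm5 by 1.40 and Pole by 1.35. The list mean of the mitosis genes was 4.95 ± 0.04 in control and 6.74 ± 0.37 in bleomycin arrays (SD, n = 4 each). Of 27 p53 targets 13 rose and 6 fell (15 and 8 adjusted over the list alone; camera adjusted p = 0.0224, and adjusted p = 0.246 with an estimated correlation). The death receptor Tnfrsf10b and the receptor Eda2r rose 3.69-fold and 3.02-fold and the mitotic gene Gtse1 3.24-fold, whereas Sesn1 fell by 0.77 and the DNA repair gene Xpc by 0.64. The p53 call was lost with quantile normalization (adjusted p = 0.0546) and within replicates 1 and 2 alone (adjusted p = 0.0935).

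Signalling lists held members that moved in both directions and were not called as wholes by camera. By fry, which does not compare a list with other genes, the TGF-beta, Wnt and BMP lists were called higher (adjusted p of 0.00175, 0.00402 and 0.0124) and the hedgehog list was not (adjusted p = 0.613). Of 21 TGF-beta targets 7 rose and 3 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.177). The TGF-beta binding protein Ltbp2 rose by 2.92 ± 0.17, Tgfb1 itself by 1.34 ± 0.13 and the transcription factor gene Snai1 by 0.99, and the oxidase Nox4 fell by 0.54 ± 0.09. Of 24 BMP pathway genes 8 rose and 2 fell (9 and 5 adjusted over the list alone; camera adjusted p = 0.485), and the median of -0.01 and the mean of 0.34 differed in sign, with the test's direction up. The median was 0.0058 with quantile normalization. The antagonist Grem1 rose, and the pathway targets Smad6 and Id1 fell by 0.93 ± 0.13 and 0.53 ± 0.09. Within replicates 3 and 4 alone Smad6 and Id1 differed by -0.66 and -0.46 and did not pass (adjusted p of 0.0549 and 0.144). With the marker covariate Smad6 differed by -0.47 (adjusted p = 0.424). Of 27 Wnt pathway genes 11 rose and 4 fell (11 and 5 adjusted over the list alone; camera adjusted p = 0.114). The secreted antagonists Sfrp1 and Dkk2 rose by 2.22 ± 0.13 and 1.98 ± 0.17, and the ligands Wnt2b and Wnt2 fell by 1.44 and 0.75. The Wnt list's median was 0.04 as deposited and -0.01 with median centring. Of 12 hedgehog pathway genes 4 rose and 1 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.864), among them the hedgehog-binding protein Hhip, up by 0.69, and the transducer Smo, up by 0.49.

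Of 27 growth factors and receptors 10 rose and 8 fell (11 and 10 adjusted over the list alone; camera adjusted p = 0.538, and called higher by fry with adjusted p = 0.00299). The EGF family ligands Ereg, Nrg1 and Hbegf rose, the latter pair by 1.51 ± 0.20 and 1.46 ± 0.20. The receptors Fgfr3 and Fgfr4 fell by 1.19 and 1.20. The list's median was 0.04 as deposited and -0.0045 and -0.01 with quantile normalization and median centring. Of 9 IGF-binding proteins and their protease 5 rose and 3 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.941), with a median of 0.24, a mean of -0.24 and a test direction of down. Igfbp3 fell from 11.10 ± 0.17 to 8.71 ± 0.30 (n = 4 each) and Igfbp6 was 2.82-fold lower, and the protease Pappa rose by 0.82.

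Enzymes of serine, proline and one-carbon synthesis rose in 8 of 14 cases and fell in 1 (9 and 2 adjusted over the list alone; camera adjusted p = 0.00125, and adjusted p = 0.272 with an estimated correlation). The mitochondrial folate enzymes Aldh1l2 and Mthfd2 rose by 1.42 ± 0.14 and 1.40 ± 0.20, and the glutamine transporter Slc1a5 fell by 0.79. Of 23 lipid genes 9 fell and 1 rose (11 and 2 adjusted over the list alone; camera adjusted p = 0.000159, and adjusted p = 0.228 with an estimated correlation). The fatty acid transporter Cd36, also an endothelial gene, fell by 1.51 ± 0.28 (-0.94 without control replicates 1 and 2), and G0s2 and the lipase Pnpla2, which regulate lipid droplet breakdown, fell by 1.41 and 0.89. A second, dimmer probe set of G0s2 fell by 0.51. Lipoprotein lipase, Lpl, rose by 1.62. The blood endothelium list, which expresses several lipid genes, was lower too, with a median of -1.05. Of 17 glycolysis genes 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.313), with the hexokinase Hk2 up by 0.85. Of 25 endoplasmic reticulum stress genes 4 rose and 4 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.858). The disulfide isomerase Pdia6 rose by 0.43 and the stress sensor Atf6 fell by 0.50. Of 31 respiratory chain genes only Ndufa4 passed, up by 0.37 (1 adjusted over the list alone; camera adjusted p = 0.144). That list passed without control replicate 4 or bleomycin replicate 2 (adjusted p of 0.0371 and 0.0369).

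Among markers of mesenchymal cell types, those of alveolar fibroblasts and lipofibroblasts fell. Of 20 measured 16 fell and none rose, with a median of -0.64 (17 and 0 adjusted over the list alone; camera adjusted p = 1.23e-10, and adjusted p = 0.246 with an estimated correlation). The amino acid transporter Slc7a10 fell by 1.67 ± 0.29, Mettl7a1 by 1.62 ± 0.24 and the sodium channel Scn3a by 1.44 ± 0.19. Pdgfra, a broad fibroblast receptor not on this list, fell by 0.43 ± 0.08 from a level of 12.58. Of 18 adventitial fibroblast markers 8 fell and 5 rose (9 and 5 adjusted over the list alone; camera adjusted p = 0.0598). Adh7 fell by 1.64 and Dpp4 by 1.43, and the collagen Col15a1 rose from 7.15 to 8.15. Dpp4 was uneven among the controls, as the epithelial and endothelial markers were. It differed by -0.89 without control replicates 1 and 2, by -0.86 within replicates 3 and 4 alone (adjusted p = 0.0628) and by -0.01 with the marker covariate (adjusted p = 0.988). This list passed with quantile normalization, with array weights, and without control replicate 4 or bleomycin replicate 1 (adjusted p of 0.0197, 0.0489, 0.0117 and 0.0482). Of 12 peribronchial fibroblast markers 6 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.0744, and called higher by fry with adjusted p = 0.00299). The growth factor Fgf18 rose by 1.36, Lgr5 by 1.11 and the steroid enzyme Hsd11b1 fell by 0.99. This list passed with median centring and without control replicate 1 or bleomycin replicate 1 (adjusted p of 0.0422, 0.0459 and 0.0478). Of 18 smooth muscle genes 8 rose and 4 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.158, and called higher by fry with adjusted p = 0.00299), with desmin, Des, up by 1.33 and Synm and Itga8 down by 1.06 and 0.85. The smooth muscle list shares 6 members with the contractile list. Of 19 pericyte genes 4 rose and 6 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.538). Postn rose by 1.86, Cspg4 by 1.37 and the receptor Pdgfrb by 0.86 ± 0.12, while Vtn fell by 0.97. The pericyte list shares 1 member each with the fibrotic fibroblast, matrix protein, basement membrane and growth factor lists. With the marker covariate Cspg4 differed by 0.69 (adjusted p = 0.43). Without control replicates 1 and 2 Vtn differed by -0.60 (adjusted p = 0.0504), and within replicates 3 and 4 alone by -0.63 (adjusted p = 0.0909). The pericyte median was 0.02 as deposited and -0.03 with median centring, and the test's direction was down. Its mean on control replicates 1 and 2 exceeded that on replicates 3 and 4 by 0.28, as the endothelial markers did by 0.91.

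Immediate early and heat shock genes, which tissue dissociation can induce, were lower in the bleomycin samples. Of 25 measured 18 fell and 1 rose, with a median of -0.57 (20 and 4 adjusted over the list alone; camera adjusted p = 1.26e-09, and adjusted p = 0.228 with an estimated correlation). Atf3 fell by 1.80 ± 0.21, Fosb by 1.33 ± 0.15 and the heat shock gene Hspa1a by 1.19 ± 0.19. Egr3 rose by 0.86 (adjusted p = 0.0262), a call that was lost without control replicate 1, 2 or 4 (adjusted p between 0.0578 and 0.0678). These transcripts were abundant in both groups, with list means of 10.45 ± 0.06 in control and 9.89 ± 0.17 in bleomycin arrays (SD, n = 4 each).

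Of the gate's own genes only Pecam1 passed, and markers of epithelium and blood endothelium, which the gate should remove, were lower. Pecam1, which encodes CD31, fell from 9.87 ± 0.55 to 8.56 ± 0.29 (n = 4 each; limma adjusted p = 0.00486), and differed by -0.85 without control replicates 1 and 2. Ptprc, which encodes CD45, differed by -0.48 ± 0.15 (adjusted p = 0.0529) and Epcam by -0.57 ± 0.18 (adjusted p = 0.0547). Both passed with median centring, without the dimmest 30% of genes, with a trended and robust eBayes and with array weights (adjusted p between 0.0329 and 0.0464), not with quantile normalization (adjusted p of 0.0788 and 0.0821). Both also passed without control replicate 4 (adjusted p of 0.00496 and 0.045), and Epcam without bleomycin replicate 4 (adjusted p = 0.0301). Epcam stood at 4.99 in control and 4.43 in bleomycin arrays, near the medians of the probe sets without a gene, so its difference is uncertain. Of 19 alveolar epithelium markers 18 fell, with a median of -1.62 (18 adjusted over the list alone; camera adjusted p = 1.21e-14, and adjusted p = 0.228 with an estimated correlation). Of 21 blood endothelium markers 18 fell, with a median of -1.05 (19 adjusted over the list alone; camera adjusted p = 1.41e-12, and adjusted p = 0.262 with an estimated correlation), among them the receptors Tek, Ednrb and Kdr by 1.69, 1.62 and 1.42. Kdr differed by -0.87 without control replicates 1 and 2, and by -0.88 within replicates 3 and 4 alone (adjusted p = 0.0819). These markers were not equal among the controls. The alveolar epithelium list averaged 9.07 on control replicates 1 and 2 and 8.20 on replicates 3 and 4, against 7.01 and 7.05 on the same bleomycin replicates. The blood endothelium list averaged 8.75 and 7.84 on these pairs of control replicates and 7.24 and 7.20 on the bleomycin pairs.

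Of 14 airway epithelium markers 4 fell (4 adjusted over the list alone; camera adjusted p = 0.0019, and adjusted p = 0.228 with an estimated correlation), including the club cell secretory gene Scgb1a1, at -2.32 ± 0.37, and Tppp3, at -1.54 ± 0.18. Of 15 general epithelial markers 5 fell (6 adjusted over the list alone; camera adjusted p = 0.00151, and adjusted p = 0.321 with an estimated correlation), including the protease gene Prss8 by 0.54. Without control replicates 1 and 2 this list was not called (adjusted p = 0.0581). Of 8 lymphatic endothelium markers 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.858), with a median of 0.12, a mean of -0.15 and a test direction of down. Lyve1 fell by 1.57 ± 0.35. It differed by -0.91 without control replicates 1 and 2 (adjusted p = 0.0672) and by -1.21 within replicates 3 and 4 alone (adjusted p = 0.0583).

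**Figure D4:**
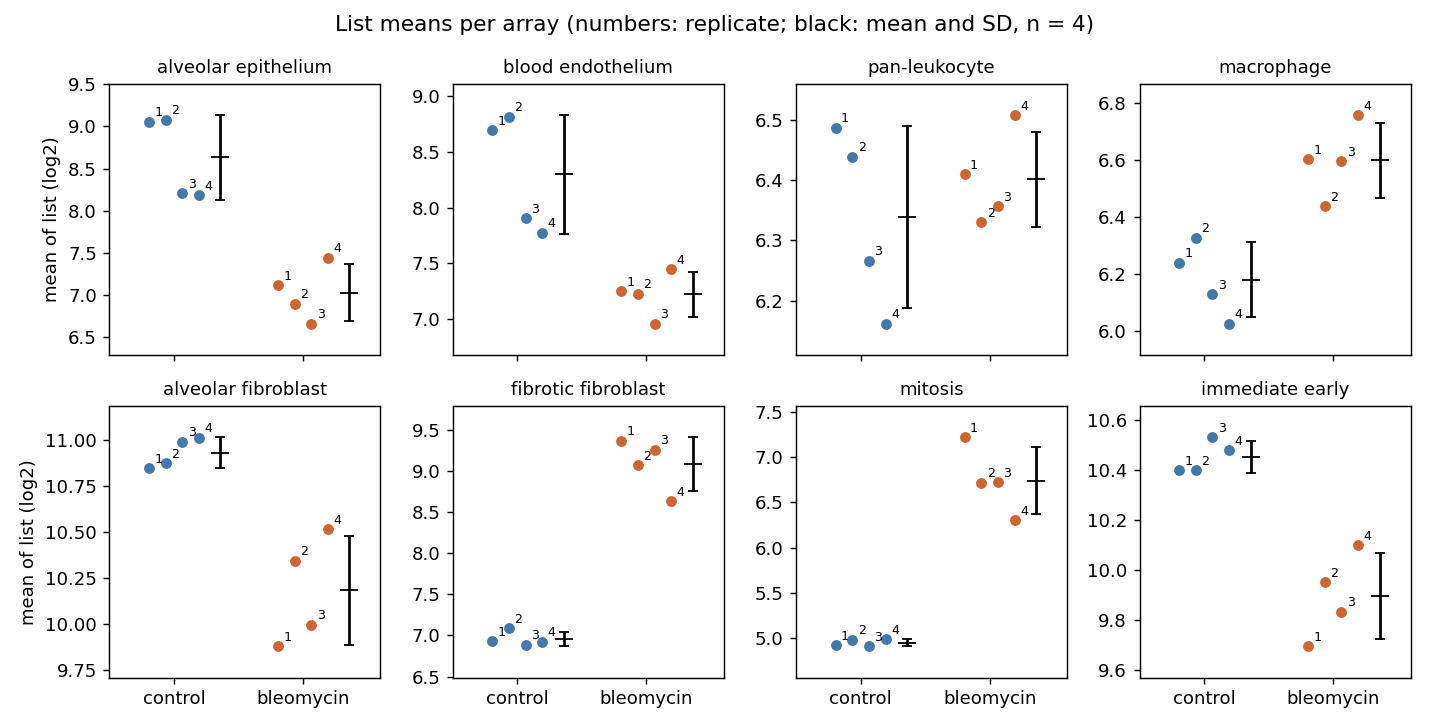
Mean log2 level of 8 gene lists on each array, numbered by replicate, with the group mean and SD (n = 4) in black; each panel has its own axis range. Alveolar epithelium and blood endothelium markers lie lower on every bleomycin array and are uneven among the controls, whose replicates 1 and 2 average 9.07 and 8.75, whereas the mitosis list lies at 4.95 ± 0.04 on the control arrays.

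Leukocyte markers did not move as one. Of 15 pan-leukocyte genes 2 rose and none fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.538). These were Fcer1g and Tyrobp, by 0.45 ± 0.13 and 0.35 ± 0.11, of which Tyrobp lost its call without any 1 of the 8 arrays (adjusted p between 0.0534 and 0.125) and Fcer1g without control replicate 1, 3 or 4 or bleomycin replicate 1, 3 or 4 (adjusted p between 0.0525 and 0.101). Within replicates 1 and 2 Fcer1g differed by 0.20 and within replicates 3 and 4 by 0.71 (adjusted p of 0.52 and 0.0556). Without control replicates 1 and 2 the list was called higher (adjusted p = 0.0478), as it was within replicates 3 and 4 alone (adjusted p = 0.0352). Macrophage genes were higher, with 13 of 24 up and 2 down (16 and 3 adjusted over the list alone; camera adjusted p = 5.65e-05, and adjusted p = 0.247 with an estimated correlation). The list mean differed by 0.24 within replicates 1 and 2 and by 0.60 within replicates 3 and 4, with control replicates 1 and 2 above 3 and 4 by 0.21. Besides C1qb, C1qa rose by 1.02 ± 0.11 and the protease Ctss by 1.56 ± 0.18, and Chil3, abundant in resident alveolar macrophages, fell by 1.44 ± 0.23 (-0.88 within replicates 3 and 4 alone). The brightest member, Lyz2, chosen after its values were seen, stood at 10.74 in control and 10.17 in bleomycin arrays (adjusted p = 0.0951), and was called lower without control replicate 4 or bleomycin replicate 4 (adjusted p of 0.0484 and 0.0353). Of 14 neutrophil genes 2 rose (2 adjusted over the list alone; camera adjusted p = 0.319, and called higher by fry with adjusted p = 0.00638), both proteases, Mmp8 and Mmp9, the latter by 1.86, that are also on the matrix protease list. The neutrophil list averaged 4.25 in control arrays, below the medians of the probe sets without a gene there, so it says little about neutrophils. Of 16 lymphocyte genes 4 fell (4 adjusted over the list alone; camera adjusted p = 0.0438, and adjusted p = 0.321 with an estimated correlation), including the B cell receptor gene Cd79a by 0.84 and the granzyme Gzma by 0.82, which differed by -1.23 within replicates 1 and 2 and by -0.41 within replicates 3 and 4 (adjusted p = 0.117). The lymphocyte call was lost without control replicate 1 or 2 or bleomycin replicate 2 (adjusted p of 0.113, 0.0738 and 0.0626), under either other scaling (adjusted p of 0.0647 and 0.0588), and without the dimmest 30% of genes (adjusted p = 0.129). It was also lost within replicates 3 and 4 alone (adjusted p = 0.325) and without control replicates 1 and 2 together (adjusted p = 0.288).

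Markers of other cells that the samples could hold were not called as groups by camera. Of 18 mesothelium genes 1 rose and 2 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.169), with Upk1b down by 0.96 and Ezr by 0.91. The mesothelium list was called lower without control replicate 4 (adjusted p = 0.0437) and within replicates 1 and 2 alone (adjusted p = 0.00826). Its mean differed by -0.29 within replicates 1 and 2 and by 0.0055 within replicates 3 and 4. Of 15 cartilage genes 4 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.341), with the transcription factor gene Sox9 up by 1.30 and Cytl1 down by 0.76. Within replicates 3 and 4 alone Sox9 differed by 0.86 (adjusted p = 0.058). Of 12 Schwann cell and nerve genes 2 rose and 1 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.538), with a median of -0.05, a mean of 0.11 and a test direction of down. The adhesion gene Ncam1 rose by 1.85 ± 0.30 and S100b by 1.18. Of 8 platelet genes 2 fell (2 adjusted over the list alone; camera adjusted p = 0.188, and called lower by fry with adjusted p = 0.0208), including Ppbp by 0.98. None of 5 erythroid genes passed (0 adjusted over the list alone; camera adjusted p = 0.429), and Rhd and Slc4a1 differed by -0.11 and 0.04 (adjusted p of 0.702 and 0.835). Only 5 of the 15 erythroid genes listed were measured. The erythroid and platelet lists averaged 4.44 and 4.68 in control arrays, near the medians of the probe sets without a gene, so both say little about these cells.

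As a check of the samples, the X-inactivation transcript Xist stood at 3.12 ± 0.30 in control and 3.25 ± 0.20 in bleomycin arrays (SD, n = 4 each). The Y-linked gene Eif2s3y stood at 7.75 ± 0.10 and 7.51 ± 0.13, Kdm5d at 6.33 ± 0.04 and 6.33 ± 0.20, and Uty at 7.25 ± 0.13 and 7.14 ± 0.11. None of these passed the test (limma adjusted p of 0.125 or more), although all 4 bleomycin values of Eif2s3y lay below the 4 control values.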

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

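The tests of splits of the arrays were written before their results were seen. The tests of technical explanations in this part were chosen only after the result was seen.

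The real grouping was compared with other splits of the arrays. Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave 3850 changed genes by limma, and the highest of the others gave 0. At an unadjusted p under 0.05 the real groups gave 6772 genes and the highest other split 2564. The other splits mix the groups, so the real difference enters their spread and lowers their counts. For that reason these counts cannot decide whether chance accounts for the number of changed genes. For the gene lists chance was not excluded either. With camera and its preset correlation, 3 of the 35 splits called at least the real number of 22 lists, and the highest other split called 24. The 16 splits that put 3 arrays of 1 group with 1 of the other, and so keep part of the real contrast, called 11 to 24 lists. The 18 splits that took 2 arrays of each group called 0 to 12. The lists share genes that move together across arrays, which is a structure of the samples that a preset correlation does not cover.

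Markers of epithelium and endothelium were lower in the bleomycin samples although the gate removes both cell types. Their brightest members, Sftpc and Calcrl, chosen after their values were seen, stood at 12.08 and 11.10 in control and 9.76 and 10.05 in bleomycin arrays, and without control replicates 1 and 2 Calcrl differed by -0.62. A larger share of every other cell type in the control samples would have left leukocyte markers lower in bleomycin samples alike. The pan-leukocyte median was 0.105 and the macrophage median 0.485. The lymphocyte median was -0.204, Ptprc differed by -0.48 and the pan-leukocyte mean by -0.0928 within replicates 1 and 2. All of these lay nearer 0 than the medians of the alveolar epithelium and blood endothelium lists. The airway and general epithelial medians, -0.242 and -0.253, lay nearer 0 than Ptprc and the macrophage median. Quantile normalization and median centring left the median nearest 0 of the alveolar epithelium and blood endothelium lists at -1.05. The array medians of the tested genes ranged over 0.071, so centring could move a list only a little. The authors' own normalization was not tested. Different amounts of epithelial and endothelial RNA carried through separate sorts may account for part of the fall. Control replicates 1 and 2 exceeded replicates 3 and 4 by 0.872 and 0.914 in these lists. None of 10000 random lists of the same size and level differed by as much. Their genes were drawn independently, whereas these markers move together (estimated correlations of 0.72 and 0.856), so that comparison cannot decide. Leukocyte lists stood higher on control replicates 1 and 2 too, by 0.249 (pan-leukocyte), 0.207 (macrophage) and 0.185 (lymphocyte). A lower number or expression of epithelial and endothelial cells in injured lungs stays open. The alveolar epithelium and blood endothelium lists also differed by -1.14 and -0.64 between the groups within replicates 3 and 4.

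Immediate early and heat shock genes were lower in the bleomycin samples. Quantile normalization and median centring did not remove it, with a median nearest 0 of -0.569, but they cannot test the authors' own normalization. Endothelial and epithelial cells rich in these transcripts, as the only cause, would have raised them on control replicates 1 and 2 by 0.377. The measured difference was -0.106. Bleomycin replicates 1 and 2 differed from 3 and 4 by -0.144, although their alveolar epithelium and blood endothelium lists differed by -0.0414 and 0.0371. An offset between these pairs of replicates may thus be mixed in. The comparison bears on the whole fall only, and a partial contribution was not excluded. Longer or warmer handling of the control lungs cannot be told apart from an effect of bleomycin, because all controls share a treatment. The 4 heat shock members had a median of -0.831 and the other 21 members a median of -0.529, so both parts may reflect either.

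Macrophage markers were higher although the gate removes CD45-positive cells and Ptprc was not higher. More leukocytes of every kind would have raised lymphocyte markers, whose median was -0.204. That list was dim (means of 5.04 in control and 4.80 in bleomycin arrays) and its call was unstable. The pan-leukocyte list was not called over all arrays. Within replicates 3 and 4 alone it was called higher (camera adjusted p = 0.0352), and also without control replicates 1 and 2. More leukocytes of every kind were thus not excluded. Under quantile normalization and median centring the macrophage median nearest 0 was 0.435, which leaves the authors' own normalization untested. Macrophages in place of other leukocytes among carried-over cells stay open, since only 4 of the 12 markers brighter over all arrays rose, against 9 of the 12 others, and of the brightest Lyz2 was not higher (10.74 in control, 10.17 in bleomycin arrays) and Chil3 fell by 1.44, while alveolar epithelium also expresses Lyz2. Carry-over that differs between samples also bears on it, as the list differed by 0.237 within replicates 1 and 2 and by 0.602 within replicates 3 and 4. A transcriptional change in the mesenchymal cells themselves was not tested and stays open.

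Single arrays stood apart from the other 3 of their group in 20 of 412 sets of 4 values, or 4.85%, about the 1 in 20 that chance gives. Of these, 6 were list means, in log2 units. The interferon list stood at 7.49 on bleomycin replicate 3 against 7.40 to 7.41 on the others. Control replicate 3 stood apart in the Wnt list at 7.09, the IGF-binding list at 9.84, the neutrophil list at 4.19 and the platelet list at 4.61. The complement list stood at 7.10 on control replicate 4.

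Among named genes, P4ha3 stood at 7.69, Igfbp6 at 10.76 and Ccl2, a chemokine gene named in the last part, at 6.32 on control replicate 2. Scgb1a1 stood at 12.12 on control replicate 1, and Actg2 at 5.37 and S100b at 4.42 on control replicate 4. Xpc stood at 6.50 and Wnt2b at 5.63 on bleomycin replicate 1, Egr3 at 8.35 on bleomycin replicate 2 and Pdia6 at 11.16 on bleomycin replicate 3. On bleomycin replicate 4, Col28a1 stood at 8.16, Id1 at 7.52, Hbegf at 7.53 and Ctss at 9.82. Without its array the difference of Egr3 was 0.60.

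Rows outside the gene test also changed. Of the 16010 rows without a gene in the annotation used, 121 were higher and 705 lower in bleomycin samples. Of the 1814 rows paired with several genes, 132 were higher and 121 lower.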

How the results depend on the processing

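The pairs of replicates 1 and 2 against 3 and 4, the fits without control replicates 1 and 2, the marker covariate and the protein-coding set were chosen after seeing the data. Genes higher in bleomycin ranged from 1497 to 1987 and genes lower from 1306 to 1883 when 1 array was left out, with 14 to 15 and 7 to 10 lists. No gene called higher was called lower, or the reverse, under any alternative. The threshold moved the counts most among choices made beforehand, as it keeps fewer genes by construction. A treat test against a 1.5-fold change left 281 higher and 100 lower, a log2 difference over 1 left 440 and 282, and an adjusted p under 0.01 left 1079 and 879. Quantile normalization gave 2567 higher and 1589 lower, or 61.8% higher against 52.5%, and median centring 1623 and 2314, or 41.2%. Camera with an estimated correlation called 0 lists higher and 0 lower. Fewer arrays were used for replicates 1 and 2 alone (838 higher, 833 lower), replicates 3 and 4 alone (503 and 220) and without control replicates 1 and 2 (1205 and 992).

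The replicate block gave 1937 higher and 1838 lower genes and 13 and 8 lists, and the p53 list lost its call (adjusted p = 0.057). The deviations of samples with the same number correlated at 0.129, 0.0631, 0.114 and 0.0647, so the numbers were not taken to pair the samples. Not every sample correlated best with its own number.

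The mean of the epithelial and endothelial markers as a covariate, which differs between the groups and so takes their difference with it, left 77 genes higher and 12 lower, with 20 lists higher and 2 lower against 14 and 8 without it. With it, list medians were 0.163 for pericyte, -0.123 for lymphocyte, 0.173 for blood endothelium, 0.388 for lymphatic endothelium and 0.119 for general epithelial genes, with reversed test directions. Of these, the pericyte, blood endothelium and lymphatic endothelium lists were called higher (adjusted p of 0.0449, 0.0305 and 0.00554) and the others were not called. The pan-leukocyte, TGF-beta, growth factor and peribronchial lists were called higher too (adjusted p of 3.04e-05, 0.0498, 0.0331 and 0.0331). The differences of Pecam1 (0.0751), Cd36 (0.117), Vtn (0.0231), Kdr (0.0793), Lyve1 (0.269), Calcrl (0.181) and Cxcl15 (0.47) also turned positive and did not pass. Of 162 named genes, 120 others lost their call. Their median absolute log2 difference went from 1.34 to 1.12 and their median standard error from 0.174 to 0.338, so the calls ended mainly with the wider error, but in 25 of them the difference shrank by over 1.5 times, most for Dpp4 (-0.015), Lamp3 (-0.057) and Ednrb (-0.105). The lists of collagen modification, lipid, alveolar epithelium and airway epithelium genes also lost their call (adjusted p of 0.0791, 0.0627, 0.13 and 0.604). Thresholds aside, for which single genes were not listed, of the alternatives chosen beforehand that keep every array, Fcer1g, Tyrobp, Ptprc and Epcam were the named genes whose call changed. Fcer1g lost its call with the replicate block and with median centring. Tyrobp lost its call with median centring and with the most variable probe set per gene. Alternatives for linear values and for probe set suffixes did not apply. The dimmest genes have no background measure here, which limits their calls.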

Other observations

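All tests in this part were chosen only after the result was seen, and the genes named here were chosen after their values were seen. Families of genes were read from gene symbols, with 29 families tested by camera and 8 called. Some members are on a list as well, such as Cxcl13, Ccl2, Cxcl15, Tnfrsf11b and Bhlhe40. TNF superfamily ligands and receptors rose in 10 of 29 cases and fell in 1 (camera adjusted p = 0.000382, and adjusted p = 0.192 with an estimated correlation). Besides Tnfsf18, the decoy receptor Tnfrsf11b, which binds RANK ligand, rose by 3.07 and Tnfrsf23 by 2.06. Of 32 chemokines 12 rose and 2 fell (camera adjusted p = 0.00284, and adjusted p = 0.286 with an estimated correlation), with the monocyte chemokine Ccl2 up by 1.82 and Cxcl15, a lung epithelial chemokine, down by 2.01. Cxcl15 differed by -1.19 without control replicates 1 and 2 (adjusted p = 0.0534) and by -1.16 within replicates 3 and 4 alone (adjusted p = 0.16). Of 48 histone genes 13 rose and none fell (camera adjusted p = 0.0093, and adjusted p = 0.286 with an estimated correlation), with the linker histone H1f5 up by 2.58 from a control level of 2.68, so dim that the size of the rise is uncertain.

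Of 17 circadian clock genes 6 fell and 2 rose (camera adjusted p = 0.0484, and adjusted p = 0.286 with an estimated correlation), with the repressor Cry2 down by 1.28 and Bhlhe40 up by 0.74. The hour of sampling is not given in the sources used here. Of 73 small nucleolar RNA genes 11 fell and 1 rose (camera adjusted p = 0.0172, and adjusted p = 0.799 with an estimated correlation), with Snora28 down by 1.31. Of the 16010 rows without a gene 705 were lower and 121 higher, so a lean downwards was not particular to these genes. The 37 interleukin receptor genes were not called (camera adjusted p = 0.745), and within them Il13ra1 rose by 1.68 and Il6ra fell by 1.70.

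Of 49 genes of proteasome subunits and their regulators 13 rose and none fell, and the other members did not pass, with a median of 0.196 (camera adjusted p = 1.73e-05, and adjusted p = 0.403 with an estimated correlation), led by Psmd10 and Psmd8 at 0.76 and 0.47. The lower median under quantile normalization and median centring was 0.146. The authors' own normalization cannot be tested this way, and the median of the rows without a gene differed by -0.229 between the groups.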
